A study of Drosophila melanogaster with 2 samples.

How the data were processed

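Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on whole Drosophila melanogaster embryos aged 0 to 4 hours after egg laying. The embryos came from a transgenic line that makes the CG7271 protein with green fluorescent protein (GFP) at its C-terminal end. Per the description, an anti-GFP antibody was used for the precipitation. The antibody label names CG7271 instead, and the description was followed here. Per the labels, chromatin was sonicated to fragments of 200 to 800 bp. The 2 libraries, biological replicates 2 and 3, came from separate biosamples of this line and form 1 group, so no comparison between groups was possible. A control experiment is named in the labels, and its library was not analysed here.

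The deposited files are 4 peak lists in narrowPeak format on the dm6 assembly. Per the deposited notes beside the files, the replicate 2 and replicate 3 lists were each called by the authors on that replicate's alignment against a control alignment. The pooled list was called on both alignments together, and the last list holds the peaks that passed an irreproducible discovery rate (IDR) threshold. IDR compares the ranks of peaks between replicates and keeps those ranked alike. The peak caller, the aligner, their versions and the IDR threshold are not given in the sources used here. The authors gave each peak a signal value, a −log10 q value and a summit position. The signal is the authors' own value per peak on a scale that is not stated, so it was used only to rank and describe peaks within a list. The deposited −log10 q values stop at an upper limit, 3.70 in the pooled list, which 2493 pooled peaks share, and were not used for ranking. Tested on the files, the 2445 IDR peaks are the 2445 pooled peaks of highest signal. They are therefore compared with peaks of lower signal from the same list. Read depth is unknown, since the files hold no read counts, and intervals cover counting error of peaks only. Both replicates were called against a control alignment upstream, which corrects for local recovery only as far as that control did.

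Transcription start sites (TSSs) and gene models were taken from Ensembl release 115, whose coordinates are those of dm6, and sequence from the RefSeq copy of the same assembly. Records of transposable elements were left out of the genes, which left 13945 protein-coding genes among 17683 genes of any type and 23517 annotated 5' ends. A promoter peak has its summit within 500 bp of any of these. Other peaks are called distal. Coordinates are given as 1-based.

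Replicates were compared over equal numbers of peaks, the 2445 highest of each, with a peak counted as shared where summits lay within 100 bp. The share expected by position alone came from 100 circular shifts of the replicate 3 list along its chromosomes. IDR peaks were set against the 27163 pooled peaks that overlapped none of them, with Fisher's exact test. Gene lists were tested with Fisher's exact test against all other genes of the same class, and the p-values were adjusted by the Benjamini-Hochberg method over 29 lists. A list of 16 motifs and the 2080 strand-merged 6-mers were sought within 50 bp of IDR summits, with windows centred 500 bp to either side as background. Counts per chromosome arm and the side of the TSS were tested with exact binomial tests, and median signals with a permutation test of 100000 resamples. All tests were two-sided. Shares have exact (Clopper-Pearson) 95% intervals, and odds ratios have 95% intervals on the log scale. Tests across peaks or genes treat them as independent, although neighbouring peaks and genes that share a summit are not. Among IDR peaks, 199 (8.14%) had another IDR summit within 1000 bp.

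The groups, tests, gene lists, motifs and most alternatives were fixed before the data were examined. Backgrounds of equal GC count, the 8-mers and the hypotheses tested besides the planned comparisons were chosen after seeing the data. The background of equal GC count is the middle of 99 random draws for the motifs, the 6-mers, the tests of the chosen 8-mer and the distal peaks. It is 1 draw for the promoter share and for the search for 8-mers. For the motifs and the 6-mers the 99 draws replaced 1 draw whose values were known. Symbols in the lists that had been renamed were matched to current ones, also after the files were read. Symbols still without a match were left out, which left 7 of 10 for pioneer and early chromatin factors, 14 of 16 for insulator and architectural proteins and 16 of 17 for the Polycomb group. It left 12 of 13 for sex determination, 9 of 10 for cellularisation and 19 of 20 for male germline genes. The symbols left out of the pioneer list were CLAMP, Psq and vfl. The genes named are the nearest gene by TSS of the 20 IDR peaks of highest signal, the 4 members with the highest signal at a promoter summit in each list called by its test, up to 2 such members in each other list, and CG7271. Some genes that this rule takes are not reported here. Genes at the same summit are named together, and genes named outside this rule are said to be so. Alternatives covered the distance to a TSS, the background, the window, a stricter list of the 1222 highest IDR peaks, and lists made without replicate 2 or without replicate 3.

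The code was tested on simulated data. A planted gene list and a planted 6-mer each came out at rank 1 by p. No motif and no 6-mer was called between left and right flanks. With summits placed at random TSSs the gene list test made on average 1.16 calls per set of 29 lists, and 1.76 with the summits at 1 TSS per gene. Most of these calls concerned genes that lie in clusters or inside other genes. In 100 sets each, the small nucleolar RNA (snoRNA) list was called higher in 74 and 93, the histone list in 5 and 33, the tRNA list in 2 and 30, and the microRNA list in 2 and 9. The cytosolic ribosomal protein list was called higher in 7 and 0, and the cuticle list lower in 8 and 1. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.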

Results

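Binding of GFP-tagged CG7271 was mapped in 2 biological replicates of whole embryos aged 0 to 4 hours. The replicate lists and the pooled list each held 30000 peaks, and 2445 peaks passed the authors' IDR threshold. Median peak widths were 364 bp in replicate 2, 376 bp in replicate 3 and 380 bp in the pooled list. The highest signal was 18.1 times the median in replicate 2, 24.4 times in replicate 3 and 22.6 times in the pooled list. How deeply each library was sequenced is unknown from these files. All IDR peaks lay on the arms X, 2L, 2R, 3L, 3R and 4.

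The IDR peak of highest signal lay at plexus (px; 2R, 22514166 to 22514461), a gene named for its effect on wing veins, with its summit 223 bp upstream of a TSS. Its signal was 1157.7, and it ranked 1 in both replicates. The next peaks lay at CG14100 (signal 1102.3, summit 78 bp upstream of the TSS) and at Ugalt, which encodes a UDP-galactose transporter (1067.9, 38 bp upstream). They were followed by a peak between the divergent genes Art3, an arginine methyltransferase gene, and mRpS10, a mitochondrial ribosomal protein gene (1035.5), and by peaks at CG1142 (943.1) and ph-p (942.9). ph-p encodes a Polyhomeotic subunit of Polycomb repressive complex 1, and this summit lay 499 bp upstream of a TSS. The other peaks among the 20 highest had as nearest genes CG5611, Tcs5, CG1888, CycY, CG1635, lncRNA:CR31044, CG11309, sp3, CG13390, mRpL41 (with lncRNA:CR44463), Lrch, lncRNA:CR44339, Chro and CycB, with signals from 911.1 down to 725.8. Among the 20 peaks, 4 were not at a promoter. The summit assigned to CycY lay in a coding exon 2810 bp from the TSS, that of Lrch in an intron at 5248 bp, and those of sp3 (583 bp) and of the mitotic cyclin gene CycB (3334 bp) were intergenic. None of the 20 ranked below 33 in either replicate list.

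To ask how far the replicates recovered the same sites, their 2445 highest peaks were compared. Replicates 2 and 3 shared 1581 of these (64.7%, exact 95% interval 62.7 to 66.6%), against a mean of 0.362% and a maximum of 0.736% after 100 circular shifts. Sharing depended on the number of peaks taken. It was 80.0% (76.2 to 83.4%) among the 500 highest and 36.0% (35.5 to 36.6%) over the full lists, where shifts gave 4.55%. Of the 2445 highest replicate 2 peaks, 90.6% had a summit somewhere in the full replicate 3 list, and 91.3% of those of replicate 3 had a summit in the full replicate 2 list. In the full lists of both replicates 2350 IDR peaks (96.1%) had a summit, while 69 (2.82%) were among the 2445 highest of neither. Peaks at promoters were not detectably more or less often shared than others. In replicate 2, 52.4% of shared and 54.9% of unshared peaks were promoter peaks (Fisher's exact test, p = 0.252), and in replicate 3 these shares were 51.9% and 52.8% (p = 0.703).

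**Figure D1:**
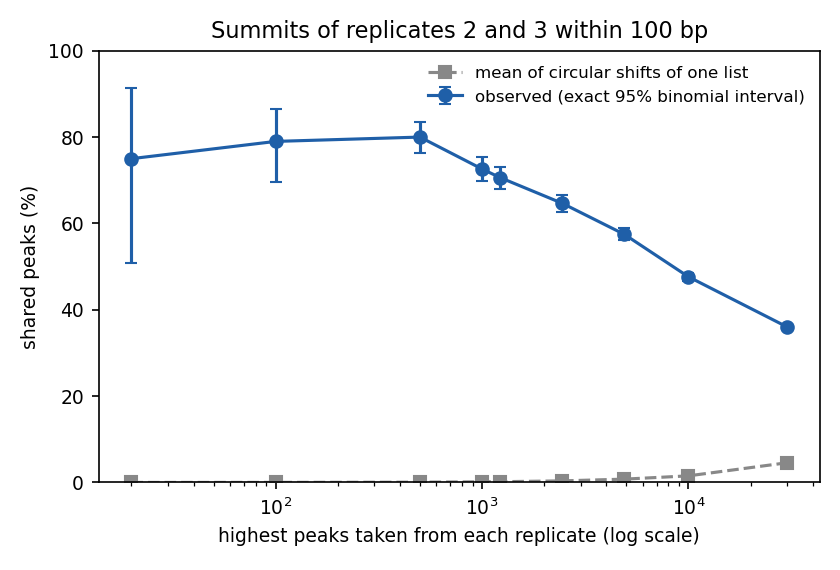
Percent of peaks shared between replicates 2 and 3 (summits within 100 bp) against the number of highest peaks taken from each list, on a log scale. Circles with bars give the observed share and its exact 95% binomial interval, and squares the mean of 100 circular shifts; the share was 80.0% for 500 peaks, 64.7% for 2445 and 36.0% for 30000.

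Promoters made up more of the IDR peaks than of the remaining pooled peaks. A TSS lay within 500 bp of 1279 of 2445 IDR summits (52.3%) and of 7543 of 27163 other pooled summits (27.8%), while 13.8% of random positions met this criterion. The odds ratio was 2.85 (95% interval 2.62 to 3.10; Fisher's exact test, p = 1.36e-130). The excess did not separate IDR peaks from the pooled peaks ranked directly below them. Of the 2445 highest other pooled peaks, 51.5% were promoter peaks (odds ratio 1.03, 0.924 to 1.16, Fisher's exact test, p = 0.587), and against the lower-ranked 13581 the odds ratio was 4.34. Summits within 500 bp of a TSS were counted as promoter whatever else they lay in, so the other places below hold distal summits only. Coding exons away from promoters held 14 IDR summits (0.573%, against 6.17% of other pooled peaks; odds ratio 0.0876, Fisher's exact test, adjusted p = 5.09e-45). Transposable elements, given last, were counted apart from these places. By the same exact test, the 3' UTRs held 1.60% against 4.55% (adjusted p = 2.22e-14), introns 29.2% against 38.7% (adjusted p = 1.44e-20) and intergenic sequence 14.6% against 20.8% (adjusted p = 6.58e-14). Since the places exclude each other, the larger promoter share by itself lowers the other shares. Among distal summits, introns held 715 of 1166 IDR and 10520 of 19620 other pooled summits, and intergenic sequence 356 and 5639. These distal counts were not tested, and they show no avoidance of introns or intergenic sequence. For 5' UTRs and exons of non-coding genes away from promoters no difference was called (exact test, adjusted p = 0.909 and 0.362). Annotated transposable elements held 1 IDR summit (0.0409%), compared with 0.880% of other pooled summits and 5.99% of random positions (exact test against the other pooled summits, adjusted p = 5.88e-08).

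Promoter summits lay mostly upstream of the start site. Of 1274 IDR summits within 500 bp of, but not at, their nearest TSS, 978 were upstream (76.8%, 74.3 to 79.1%; exact binomial test, p = 1.99e-85). Their median position was -83 bp, with quartiles of -156 and -5 bp. Among the other pooled peaks the share was 56.5% (55.4 to 57.6%) and the median position -23 bp. The authors' signal did not detectably differ between the 1279 promoter peaks (median 158) and the 1166 distal peaks (median 156) of the IDR list. The difference of medians was 2.40 (permutation test, p = 0.319). With TSSs within 200 bp it was -1.24 (permutation p = 0.543), and in the list made without replicate 2 it was 3.53 on the signal scale of replicate 3 (permutation p = 0.00402).

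**Figure D2:**
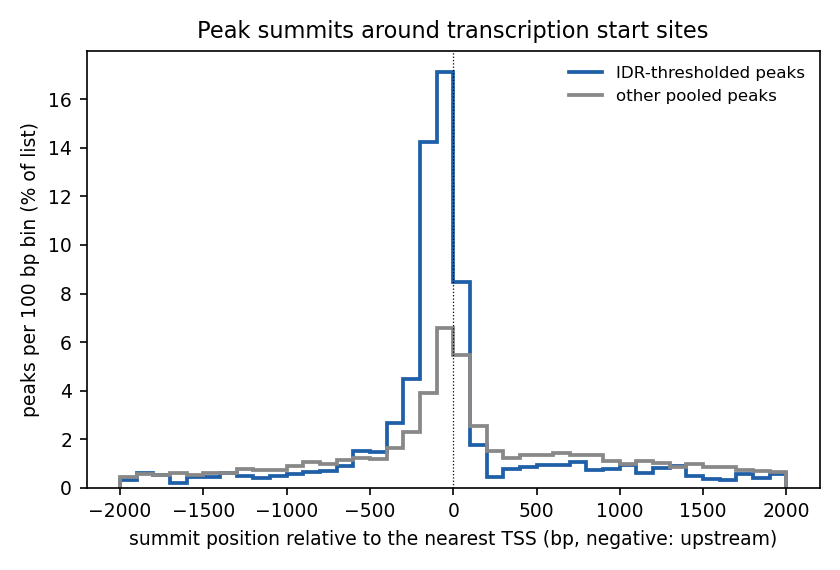
Position of summits relative to the nearest TSS in bp, negative values upstream, as the percent of each list per bin of 100 bp, for the 2445 IDR peaks and the 27163 other pooled peaks. The bin from -100 to 0 bp held 17.1% of IDR peaks and 6.59% of other pooled peaks, and the bin from -200 to -100 bp held 14.2% and 3.89%.

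To describe which genes carried these peaks, IDR summits within 500 bp of a TSS were assigned to genes. They covered 1678 of 13945 protein-coding genes (12%). Among the 29 lists, cytosolic ribosomal protein genes stood highest. A promoter summit lay at 74 of 93 of them (79.6%), compared with 11.6% of other protein-coding genes (odds ratio 29.7, 17.9 to 49.4; Fisher's exact test, adjusted p = 1.75e-49). The 74 genes had 76 different summits with a median rank of 370. Among the highest were those at RpS27, together with Nup37 and sisRNA:CR46364 (rank 23, signal 702.9), at RpL14 with Nelf-E and snoRNA:U49:66Da (rank 34, 651.0) and at RpL24 (rank 47, 558.4). Summits lay 16, 14 and 11 bp from the TSS of the ribosomal protein gene. With replicate 2 alone the highest 2445 peaks covered 72 of these genes, and with replicate 3 alone 70. Mitochondrial ribosomal protein genes, led by mRpS10 and mRpL41, had a summit at 14 of 73 (odds ratio 1.74, Fisher's exact test, adjusted p = 0.116; without replicate 2, 2.05, adjusted p = 0.0459), and proteasome subunit genes at 3 of 48 (Rpn3 with l(2)37Bb and Rpn2 with Slbp among them).

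Genes for insulator and architectural proteins, which shape chromosome domains, carried promoter peaks in 8 of 14 cases (odds ratio 9.79, 3.39 to 28.2; Fisher's exact test, adjusted p = 0.000321). Chro, which encodes a chromodomain protein of polytene interbands, shared the peak of rank 19 with Ssl1. Cp190, a cofactor of insulator proteins, had rank 101 with CG4338, Dref, whose product binds the DNA replication-related element, had rank 182 with RpL13, and CTCF had rank 1487. Cell cycle and replication genes had peaks in 9 of 30 cases (odds ratio 3.14, exact test, adjusted p = 0.0225), led by tefu, the ATM kinase gene, with Hsc70-4 (rank 992), the origin recognition gene Orc5 with Arpc1 (1232), the mitotic kinase gene aurA with CG3281 (1262) and CycB (1332). Segment polarity genes had 5 of 12 (odds ratio 5.23, exact test, adjusted p = 0.0252), with the Wnt receptor gene fz at rank 346, nkd at 470, ci with asRNA:CR43957 at 949 and wg at 1799. Genes that count X chromosomes or determine sex also had 5 of 12 (the same odds ratio and adjusted p), with the corepressor gene gro at 758, the sex switch gene Sxl at 1314, emc at 1903 and dpn at 2312. Cellularisation genes had 4 of 9 (odds ratio 5.86, exact test, adjusted p = 0.0386), with term at rank 489, Z600 with gdl and gdl-ORF39 at 573, slam at 2120 and Sry-delta at 2364. Whether Sry-delta itself acts in cellularisation was not checked, and the test was not repeated without it. The summit at term lay 5164 bp from the TSS of CG7271, the tagged gene, where a transgene copy can add signal. Nor was the test repeated without term. The calls of the smaller lists depended on the setting. Without replicate 2 the exact test no longer called segment polarity genes (odds ratio 3.64, adjusted p = 0.106) and sex determination genes (2.42, adjusted p = 0.246), and cellularisation genes stood at 14.6. Without replicate 3 the exact test did not call cell cycle genes (2.20, adjusted p = 0.156) and sex determination genes (2.41, adjusted p = 0.237). By nearest gene at any distance cell cycle genes were not called either (2.17, exact test, adjusted p = 0.133). Cellularisation genes were not called with TSSs within 200 bp (4.99) or 1000 bp (5.03). Against only genes with a pooled peak at their promoter, ribosomal protein (odds ratio 18.0) and insulator genes (5.63) were called, and among the 1222 highest IDR peaks only ribosomal protein genes were (30.2).

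Other regulators of early development had promoter peaks at numbers that the test did not call. By Fisher's exact test, Polycomb group genes had 5 of 16 (ph-p and E(z), the latter with Cnep1r2 at rank 144; adjusted p = 0.0679), Enhancer of split complex genes 4 of 11 (E(spl)m2-BFM at 237 and E(spl)m7-HLH at 238; adjusted p = 0.0679) and pioneer and early chromatin factors 3 of 7 (opa at 1160 and Trl with CG42507 at 1654; adjusted p = 0.0759). In the list made without replicate 3 the pioneer factors were called (odds ratio 9.66, exact test, adjusted p = 0.0181). Polycomb group genes were called with TSSs within 1000 bp (4.89, exact test, adjusted p = 0.0103). Pair-rule genes had 3 of 11 (ftz at rank 93 and opa), gap and head gap genes 1 of 11 (kni at 1158), dorsoventral patterning genes 3 of 20 (brk at 1484 and ush at 1937), Hox genes 0 of 8 and maternal effect genes 5 of 26 (plu with RpS18 at 139 and cact at 663). With each peak given to its nearest gene at any distance, the exact test called gap (odds ratio 8.57, adjusted p = 0.00406), pair-rule (the same values), dorsoventral (3.85, adjusted p = 0.0202) and Hox genes (11.9, adjusted p = 0.00414) higher. This setting makes no allowance for the length of sequence around a gene. Against other distal pooled peaks, counted per peak, the odds ratios were 1.74 for gap (not called), 2.16 for pair-rule, 2.43 for dorsoventral and 1.90 for Hox genes. Heat shock genes had 3 of 17, with Hsp83 at rank 82 and Hsp27 at 248. Neuronal differentiation genes had 1 of 15 (elav with lncRNA:enrr at 258), muscle structural genes 2 of 15 (sls at 1087 and Tm1 at 2055) and male germline genes 0 of 19. The chorion protein list had 1 of 11, and that gene was Cp190, taken in by its symbol although it encodes no chorion protein.

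Promoter peaks were less frequent in 6 lists. They were found at 7 of 290 tRNA genes (2.41%; odds ratio 0.213, Fisher's exact test, adjusted p = 6.03e-06), at 1 of 115 histone genes, the variant histone gene His2Av with ball (rank 1143; adjusted p = 9.33e-05), and at 8 of 260 microRNA genes (3.08%; adjusted p = 0.000111). The 5' ends of microRNA genes are those of the annotated precursors, so promoters of longer transcripts that hold them were not measured. No promoter peak was found at 93 cuticle protein genes (exact test, adjusted p = 0.000106), 59 odorant receptor genes or 60 gustatory receptor genes (both adjusted p = 0.00349). Among tRNA genes the highest summits were near tRNA:Tyr-GTA-1-8 with CG8036 (rank 186) and tRNA:Phe-GAA-1-2 with RpL17 and snoRNA:Psi28S-1232 (rank 334), followed by tRNA:Phe-GAA-1-4 with tRNA:Phe-GAA-1-5 (rank 1555). Among microRNA genes they were near mir-9378 (rank 309) and near mir-6-2 and mir-6-3 (rank 585), followed by mir-iab-4 with mir-iab-8 (rank 927). Small nuclear RNA genes had 0 of 32. For snoRNA genes, 17 of 269 had a peak (odds ratio 0.584, exact test, adjusted p = 0.0679), the highest being snoRNA:U49:66Da and, with RpL28 and eIF1, snoRNA:Or-CD11a (rank 119). They were called lower with TSSs within 200 bp (0.324, exact test, adjusted p = 0.00402) and by nearest gene at any distance (0.208, adjusted p = 3.79e-06), and higher with TSSs within 1000 bp (1.67, adjusted p = 0.00943). Lists of clustered or nested genes share summits, and with random summits at 1 TSS per gene the snoRNA, histone and tRNA lists were called higher in 93, 33 and 30 of 100 sets. The cuticle list was called lower in 8 of 100 sets of summits at any TSS. Against genes with a pooled peak at their promoter, tRNA genes alone were called lower (odds ratio 0.173), and without replicate 3 they stood at 0.399. The histone list had no test against that background. How well reads could be placed on repeated copies of genes is not known from these files.

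**Figure D3:**
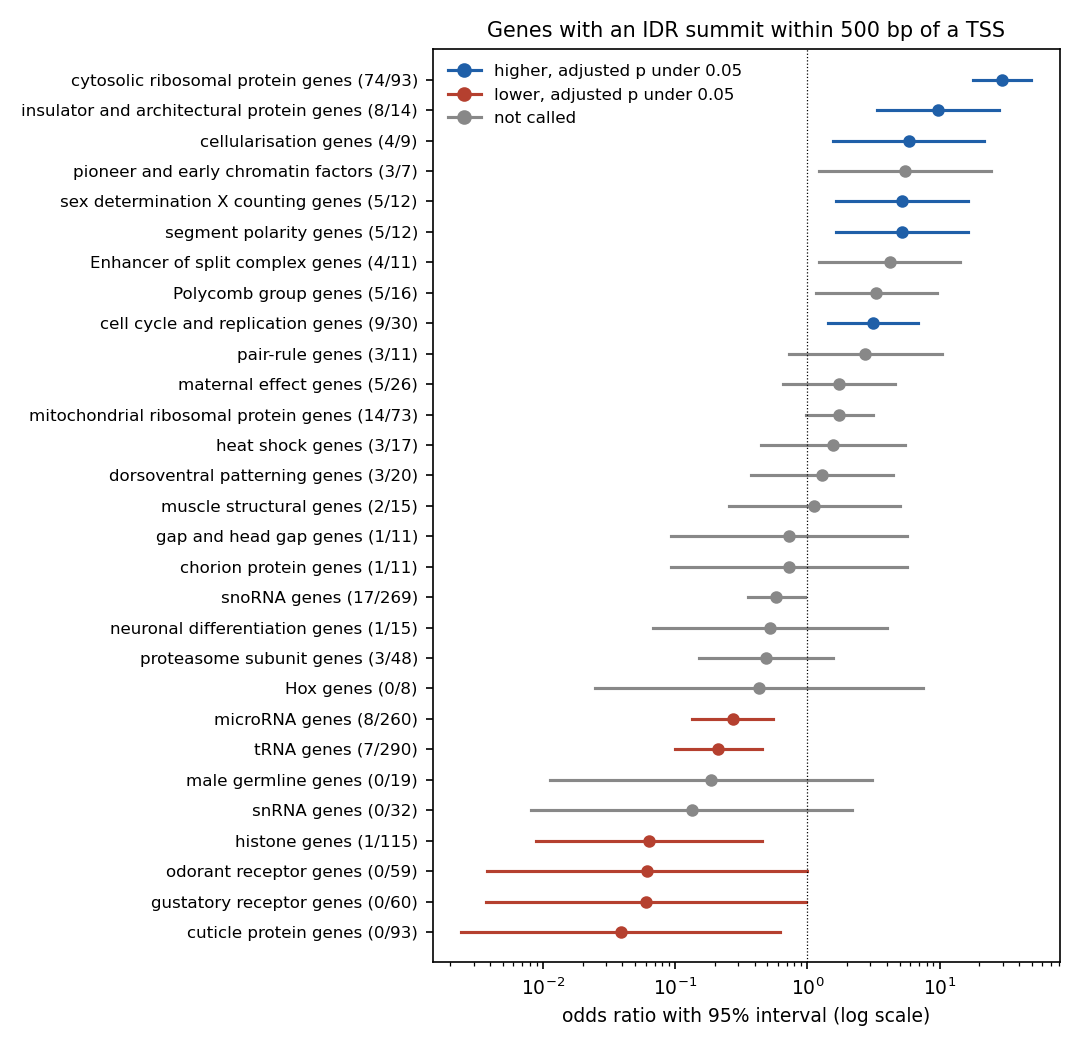
Odds ratio, on a log scale with its 95% interval, of having an IDR summit within 500 bp of a TSS for the members of each of 29 gene lists against other genes of the same class, with the number of members that had a peak and the number of members. Blue and red mark lists called higher and lower at an adjusted p under 0.05, 6 each, and grey the others; cytosolic ribosomal protein genes stood at 29.7.

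To ask which sequences lay at the summits, 16 motifs fixed in advance were sought within 50 bp. The DNA replication-related element (DRE, TATCGATA), the target of the Dref protein, was present at 2.21% of IDR summits and in 0.368% of flanking windows (odds ratio 6.11, 3.58 to 10.4; Fisher's exact test, adjusted p = 4.9e-12). The motif of the promoter protein M1BP (GGTCACAC) was present at 1.60% and 0.245% (6.59, 3.44 to 12.6; exact test, adjusted p = 1.63e-09), and core promoter motif 7 at 2.04% and 0.736% (2.81; adjusted p = 1.02e-05). The exact test called none of these 3 motifs among IDR peaks over 500 bp from a TSS, where their odds ratios were 0.857, 0.50 and 0.874 (adjusted p = 1, 0.975 and 1). A TATA box was present at 22.7% and 10.9% (2.39; exact test, adjusted p = 1.95e-37), and the Dorsal site was rarer at summits (0.0818% and 0.409%; adjusted p = 0.0406). The site of the early activator Zelda was found at 0.491% of summits and in 0.777% of flanks (odds ratio 0.630, exact test, adjusted p = 0.258; without replicate 2, 1.00, adjusted p = 1; without replicate 3, 1.15, adjusted p = 0.702). The call of the Dorsal site was lost without replicate 2 (0.525, exact test, adjusted p = 0.379), and motif 6, which was not called with both replicates (1.72), was called without replicate 3 (20.1, adjusted p = 0.000411).

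Base composition differed between these windows. GC content was 34.9% ± 10.7 (SD over 2445 windows) at IDR summits, 43.2% ± 10.6 in flanks and 40.2% ± 10.3 at other pooled summits. Pooled summits of equal GC count, a background added after seeing the data, were drawn at random 99 times, and the draw with the middle odds ratio is given for each sequence. The TATA box stood at 1.01 (exact test, adjusted p = 1; called in 0 of 99 draws) and the Dorsal site at 0.222 (adjusted p = 0.208; called lower in 9). DRE stood at 2.38 (no lower than 1.60 in any draw; exact test, adjusted p = 0.0078) and was called in 91 draws, and M1BP at 2.46 (1.57 to 4.39, adjusted p = 0.0135) in 66. Motif 7 was not called in its middle draw (1.68, 1.19 to 2.98 over the draws; exact test, adjusted p = 0.168) and was called in 28. These backgrounds were not matched for distance to a TSS. In 1 draw of equal GC count 28.3% of the summits were promoter summits, against 52.3% of IDR summits. How much of the excess of DRE and M1BP comes from the larger promoter share was not tested. Of 2080 6-mers, 338 were more and 781 less frequent at summits than in flanks, led by A/T-rich words such as AAATAT (34.4% and 16.3%, odds ratio 2.69). With equal GC count a middle number of 18 per draw was more frequent (9 to 28) and of 6 less frequent (0 to 15). The leading ones were CCGGAA (6.09% and 2.21%, odds ratio 2.87, exact test, adjusted p = 7.08e-09), ACCGGA (4.83% and 1.60%, 3.13, adjusted p = 7.12e-08) and CGGAAA (10.5% of summits, 1.97, adjusted p = 4.26e-07), each called higher in 99 of 99 draws.

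**Figure D4:**
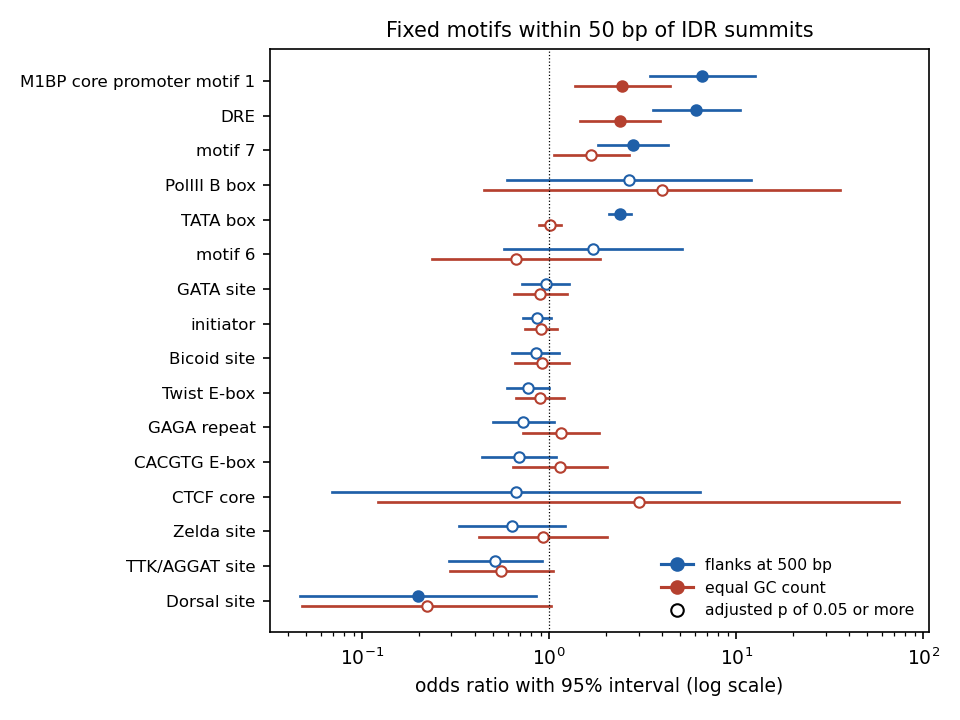
Odds ratio, on a log scale with its 95% interval, of 16 motifs within 50 bp of IDR summits, against flanks at 500 bp (blue) and against other pooled summits of equal GC count (red; for each motif the middle of 99 draws); filled symbols have an adjusted p under 0.05. The TATA box falls from 2.39 to 1.01 between the backgrounds, while DRE is at 6.11 and 2.38 and M1BP at 6.59 and 2.46. Neither background was matched for the share of promoters.

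Arm 2L held more IDR peaks than its share of bases and X and 2R fewer. Arm 2L had 517 peaks (21.1% against 17.6% expected, ratio 1.20, exact binomial test, adjusted p = 2.11e-05), X had 341 (13.9% against 17.6%, ratio 0.794, adjusted p = 8.83e-06) and 2R had 412 (16.9% against 18.9%, ratio 0.891, adjusted p = 0.0182). Arms 3L (543), 3R (616) and 4 (16) were not called. Against the distribution of the other pooled peaks the call for X was lost (ratio 0.957, exact binomial test, adjusted p = 0.468), while arm 4 was called lower (0.373, adjusted p = 2.73e-05) and 3R higher (1.08, adjusted p = 0.0367). Arm 3L was called higher against the distribution of protein-coding TSSs (1.15, exact binomial test, adjusted p = 0.000817) and among the 1222 highest IDR peaks (1.14, adjusted p = 0.0251). The call for 2R was lost in the lists made without replicate 2 (exact binomial test, adjusted p = 0.0702) and without replicate 3 (adjusted p = 0.119).

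The locus of the tagged gene was examined because a transgene copy can add signal there. CG7271 (FBgn0036791) lies on the + strand of 3L from 18588759 to 18590165, with 1 annotated transcript start. No summit of any list lay inside the gene. A pooled peak (18588476 to 18588855) had its summit 93 bp upstream of the TSS but ranked 2824, below the IDR threshold. It ranked 10602 in replicate 2 and 1160 in replicate 3. Within 20 kb on each side the pooled list had 10 peaks, against 9.80 expected from the density of the arm, and 1 was an IDR peak, at the neighbouring gene term (summit 18593923, rank 489).

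**Figure D5:**
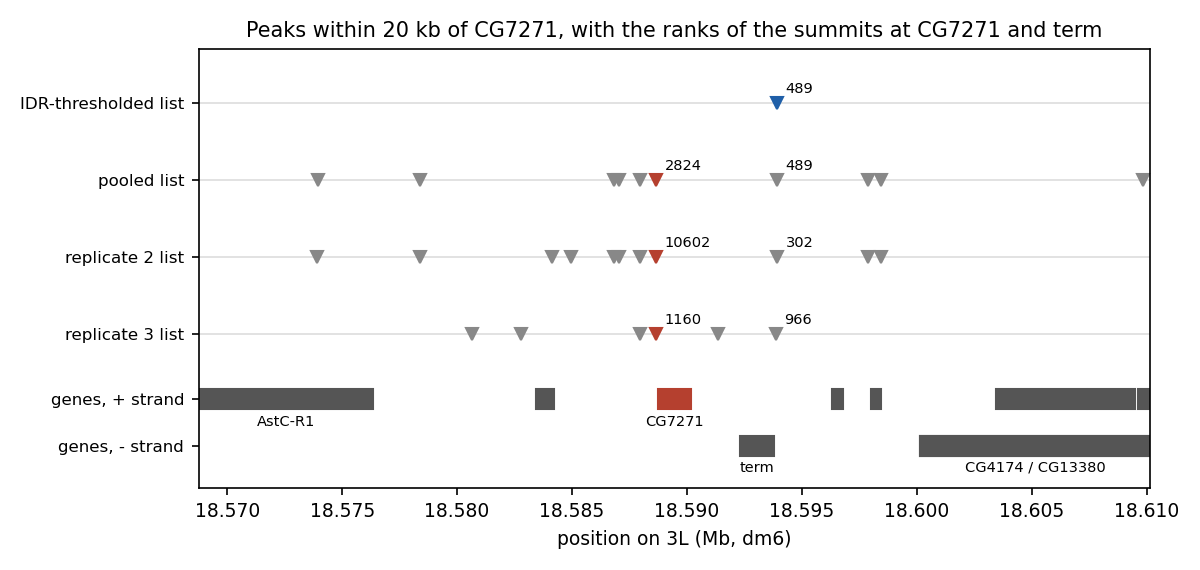
Summits (triangles) of the 4 lists within 20 kb of CG7271 on 3L, with position in Mb (dm6), above the annotated genes of each strand; numbers give ranks in each list for the summits at CG7271 (red) and term. The IDR list holds the summit at term, rank 489, and the summit upstream of CG7271 ranks 2824 in the pooled list.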

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

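Backgrounds of equal GC count were chosen only after the data were seen, and all other tests here were planned. Depth is unknown, so no limit from read numbers can be given. No paired analysis was possible because the samples form 1 group. The cause of a change was not tested unless its construction shows it. Sharing between replicates was 69.4% with an overlap of at least 1 bp, 80.0% among the 500 highest peaks, 70.6% among 1222 and 57.5% among 4890. The odds ratio of promoters was between 2.38 and 4.34 except against the highest other pooled peaks (1.03). The number of gene lists called higher and lower, 6 each, was 2 and 1 against genes with any pooled peak, where the histone list had no test. It was 1 and 2 among the 1222 highest IDR peaks, where fewer peaks were used. The nearest gene at any distance makes no allowance for the length of sequence around a gene. With it, gap genes (odds ratio 8.57), pair-rule genes (8.57), dorsoventral genes (3.85) and Hox genes (11.9) were called higher and snoRNA genes lower (0.208). The calls for cell cycle genes (2.17), odorant receptor genes (0.249), gustatory receptor genes (0.508) and microRNA genes (0.617) were lost. Cell cycle genes stood at 0.510 among the 1222 highest peaks and snoRNA genes at 0.324 with TSSs within 200 bp and 1.67 within 1000 bp, called in both. Gap genes, never called by promoter, moved from 0.731 to 1.61 without replicate 2, and dorsoventral genes from 1.29 to 0.177. Away from promoters 1 of the 4 motifs called higher was called, with DRE at 0.857, M1BP at 0.50 and motif 7 at 0.874. The 1 motif called lower became 2 with windows of 100 bp and with other pooled summits, 0 with equal GC count (1 draw, or each motif at the middle of 99) and 0 among the 1222 highest peaks, and 1 to 2 when either replicate was left out. The 338 6-mers called higher and 781 called lower became 181 and 311 against other pooled summits, 190 and 289 away from promoters, 18 and 7 in 1 draw of equal GC count, and 17 and 0 with each word at the middle of 99 draws. Over these draws 0 to 3 motifs were called higher, and 2 of the 4 with each at its middle. Arms called higher rose from 1 to 2 against other pooled peaks, against protein-coding TSSs and among the 1222 highest peaks. Arms called lower went from 2 to 1 among the 1222 highest peaks, and were 1 and 1 without either replicate. The difference in median signal was -1.24 with TSSs within 200 bp, and 1.79 to 3.53 when a replicate was left out. At the tagged gene, 3 IDR peaks lay within 50 kb. Upstream summits stayed between 73.2% and 82.1% of promoter summits. Of the alternative values of single lists, motifs, 6-mers and arms, 403 stayed on their side of the threshold, 33 of them uncalled values that crossed 1. The call was lost for 57 and gained for 19, and 7 changed direction with a call in at least 1 of the settings.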

Other observations

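All genes named in this part, the paralogue pairs, the 8-mer, the equal-GC test near patterning genes, the signal test of the 8-mer and the test of coding exons over whole ribosomal protein genes were chosen only after the result was seen, and the other tests were written down before their results but for patterns already noticed in these data. Equal-GC tests first used 1 matched draw, which proved unstable, and the middle of 99 draws replaced it after those first values were known. The search for 8-mers and the promoter share kept 1 draw. The excess of promoters was also tested (odds ratio 2.78 at equal GC count, 1.03 against the highest other pooled peaks) and is not weighed further, a choice made with these values known. The design has 1 group and gives no biological contrast, so none was tested. For binding at the 8-mer a difference in signal alone was examined, which cannot decide it, and the patterns weighed are hypotheses.

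Where a name marks a pair of related genes, such as RpS5a and RpS5b, 11 of 13 pairs had an IDR peak at 1 member and 2 pairs, RpL34a with RpL34b and RpS14a with RpS14b, at both. The members without a peak were RpL10Aa, RpL22-like, RpL24-like, RpL37-2, RpL7-like, RpLP0-like, RpS10a, RpS15Ab, RpS19b, RpS28a and RpS5b. Of the 19 ribosomal protein genes without an IDR peak, 15 had a lower pooled peak, as RpS2 at rank 3109 and RpL36A at 3209, and 4 had none. Members of this list were taken by gene name. Whether those named -like encode cytosolic ribosomal proteins was not checked.

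Away from promoters, IDR peaks lay near patterning genes. Of 1166 distal IDR summits, 64 (5.49%) had a gap, pair-rule, segment polarity, dorsoventral or Hox gene as nearest protein-coding gene, and these belonged to 36 of 62 genes. The GATA cofactor gene ush had 6 such peaks, Antp and the T-box gene Doc2 had 4 each, and Ubx, abd-A, Abd-B, oc and tup had 3 each. The highest were near ftz (rank 77, 6700 bp from the TSS), Antp (117, 18346 bp), sim (120, 4178 bp), slp1 (122, 2202 bp) and knrl (140, 3124 bp). By list, dorsoventral genes (odds ratio 2.43, Fisher's exact test, adjusted p = 0.00427), pair-rule genes (2.16, adjusted p = 0.0338) and Hox genes (1.90, adjusted p = 0.0338) were more frequent than among other distal pooled peaks, and gap genes (1.74, adjusted p = 0.111) and segment polarity genes (1.36, adjusted p = 0.395) were not called.

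For all patterning lists together the odds ratio against other distal pooled peaks was 1.98 (1.52 to 2.58, Fisher's exact test, p = 3.22e-06). Base composition as the whole cause is argued against by 2.06 (1.34 to 3.17) at equal GC count, the middle of 99 matched draws that ranged from 1.35 to 3.17. Against as many of the highest other distal pooled peaks it was 1.59 (1.07 to 2.38), so a general recovery of open regulatory regions near these genes may contribute and cannot be told apart, since no library without the tagged protein was analysed here. Peaks near the same gene are not independent, which makes these p-values too small.

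The ribosomal protein peaks raise the question of a technical source. Reads from pseudogenes or transcripts would place summits in coding exons, and of the 79 IDR summits in or within 500 bp of these genes over their whole length, 0 (0%, exact 95% interval up to 4.56%) lay there, while coding exons made up 29.3% of those bases. The exact 8-mer AACCGGAA may contribute, and other shared sequences or variants of it were not tested. It was present at 5 of 76 promoter summits (6.58%) and at 1.91% of other promoter summits (odds ratio 3.61, 1.33 to 9.79, Fisher's exact test, p = 0.0217). General recovery of open, transcribed promoters cannot be told apart from binding without a library lacking the tagged protein, and 6 of the 19 members without an IDR peak had a summit among the next 2445 pooled peaks.

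Because the leading 6-mers overlap, a longer word was sought on the arms X, 2L, 2R and 4 in 1 draw of equal GC count. There AACCGGAA had the lowest p of 31209 8-mers (2.64% of summits against 0.389%; Fisher's exact test, adjusted p = 0.0564), which missed the threshold, as 0 8-mers passed it. CGGAAACG and CCGGAAAC had the same adjusted p, so the choice of word may depend on the draw. Over all arms, also in 1 draw, 17 8-mers were called in either direction. AACCGGAA ranked 2 there, below CGGAAACG (3.48% and 0.245%, exact test, adjusted p = 9.89e-15). On 3L and 3R AACCGGAA was present at 2.85% of summits and 0.345% of windows of equal GC count (odds ratio 8.46, 2.99 to 24.0, middle of 99 draws from 3.37 to 69.0). However, 8-mers had been explored over all arms before this split, so 3L and 3R are not independent evidence. Over 500 bp from a TSS the odds ratio of AACCGGAA was 8.04 (3.16 to 20.5), which argues against promoter sequence in general as the whole cause. Without annotated transposable elements and windows with several copies it was 6.44 (3.30 to 12.6). That filter kept 2439 of 2445 summits, so it says little about repeats of other kinds. Both values include the arms on which the word was chosen, which favours high odds ratios. The 67 IDR peaks with the word had a median signal of 185 and the others 157 (difference 28.8, permutation test, p = 0.00382). However, the word was chosen for its excess in IDR peaks, which are the pooled peaks of highest signal. A higher signal within the list can follow from that choice, so this difference is not separate evidence of binding. The word contains the core GGAA of ETS-family sites, and a candidate explanation is that CG7271 or a partner binds it, which would concern 2.74% of the IDR peaks. Counted from the start of the word, positions 11 to 14 most often held G, G, A and A (56.6%, 51.3%, 52.6% and 53.9% of 76 sites). The sequence may therefore extend beyond the 8-mer, and which of the overlapping words is bound, if any, was not tested.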
